A study of Mus musculus with 6 samples.

How the data were processed

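RNA was measured by sequencing in 6 libraries of B16F10, a mouse melanoma cell line. The labels put 3 libraries in the wild-type group (WT, replicates 1, 2 and 3) and 3 in a group in which the gene for annexin A10 was knocked out (A10KO, replicates 1, 13 and 14, numbered as in the labels). Whether these numbers stand for clones, separate cultures or repeated preparations is not stated, so p-values measure only the spread between these libraries, which may be technical, at least in WT. The chromosome medians reported below differed between the A10KO libraries, which argues against repeated preparations of a single A10KO culture. Per the labels' protocols, total RNA was extracted with Trizol and treated with DNase I, and libraries followed the standard Illumina preparation. Per the submitters' processing notes, fastp, HISAT and RSEM were used with the genome build GRCm38.p5. Their versions, settings and roles are not given in the sources used here, nor is the strand setting.

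The deposited values are TPM, a unit scaled by transcript length and by the total of the library, as read from the values themselves, although the series table is presented as raw counts. They carry decimals, the columns sum to between 969834 and 985045, and the smallest values fall as gene length rises. TPM keeps no record of depth, so the depth of each library is unknown and no interval or detection limit from counting is given. Each library's own table held the same values as the series table in 6 of 6 cases. The table has 51912 genes, of which 28295 were listed at 0 in every library. Genes were named as in the table. Coordinates came from the GENCODE M21 annotation of GRCm38, matched by gene identifier for 51719 genes.

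The design written before the data were examined assumed counts. Count models were not run because the unit is TPM. The test used in their place was the one planned for a normalized unit, limma with a mean-variance trend (version 3.58.1, in R 4.3.3) on log2(TPM + 1), with TPM as deposited. Genes with at least 1 TPM in at least 3 libraries entered the test, which left 12068. Log2 changes and adjusted p-values come from this fit. Adjusted p-values are Benjamini-Hochberg values and the threshold was 0.05. Log2 changes are knockout minus wild type on the log2(TPM + 1) scale, which understates the change of low genes. The estimated prior degrees of freedom were 3.5.

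Gene lists were fixed before the data were examined. Of 41 lists, 37 had at least 3 tested members and were tested with camera in limma at a preset inter-gene correlation of 0.01. Camera compares a list with all other tested genes. The same lists were run with an estimated correlation and with fry, a rotation test of whether the members of a list move on balance one way. For each list, counts of members past the threshold were made over all genes tested and adjusted over the list alone. The values of 1 member of the interferon list are not reported here, though it stays in the counts and tests.

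The rule for naming genes, also written beforehand, took the target genes Anxa10, Prkd1 and Trim41, the called genes with the largest changes (12 per direction) and the highest levels (6 per direction), and up to 4 called members of each list. Genes taken by size had to lie on the same side in all libraries, with a mean of at least 5 and no predicted or clone-style name. For described lists with no called member it took up to 2 members with the highest mean. With 5 called genes, the rule left most members of the lists unnamed, and each further gene that is named was chosen after its values were seen.

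Chromosome medians were computed over 9352 genes with a mean of at least 5 TPM. Each knockout library was set against the mean of the wild-type libraries and each wild-type library against the mean of the other two, and the library's median over all genes was subtracted. Intervals are 95% bootstrap intervals from 1000 draws over genes, which are not independent replicates. The spread over chromosomes was compared with 10000 random reassignments of genes to chromosomes.

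The scripts were tested on simulated data for the comparison of A10KO with WT, with 11895 genes tested. Of genes changed 2-fold, 46.3% were recovered, with 91.0% of those changed 4-fold and 87.9% of those changed 8-fold, and 13 unchanged genes were called. The simulation changed 67, 67 and 66 genes at these folds, taken only from genes with higher levels. Each gene had the same SD in both groups, whereas the real A10KO libraries varied more than the WT libraries. These shares therefore do not give the power of the real comparison. A shifted list was called and 0 of 20 unshifted lists were. The simulated genes varied independently of each other, so this does not show how camera behaves on lists whose members move together. A simulated shift of -0.40 on chromosome 2 came back as -0.39. Of 60 simulated libraries with no shift, 7 had a permutation p under 0.05 for the spread over chromosomes, more than the 3 that an exact p would give.

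Alternatives planned before the data were examined were no filter, a pseudocount of 0.1, each library left out in turn, the estimated correlation and fry. Those added later were median-of-ratios, trimmed-mean (30% of log ratios and 5% of levels trimmed at each end) and quantile scaling, removal of mitochondrially encoded transcripts, a filter at 5 TPM, robust empirical Bayes, array quality weights, removal of chromosome medians, and a second form of the leave-one-out fits. In the planned form, run first, the filter was reapplied to the 5 remaining libraries. In the second form, chosen after those counts were seen, the 12068 genes were kept.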

Results

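The series asked how annexin A10, a calcium-dependent membrane-binding protein, acts on protein kinase D1 and the ubiquitin ligase TRIM41 in the spread of melanoma. The data were TPM values from 3 wild-type and 3 annexin A10 knockout libraries of B16F10, a pigmented mouse melanoma line. The depth of the libraries is unknown. Between 11889 and 12236 genes per library reached 1 TPM.

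The target gene gave no check of the labels. Anxa10 (ENSMUSG00000031635, GRCm38 chromosome 8, 62057042 to 62123150) was listed at 0 TPM in all 6 libraries, wild type included. Prkd1 (ENSMUSG00000002688, chromosome 12, 50341231 to 50649098), which encodes protein kinase D1, was also listed at 0 in all 6. Of 22 genes for RNA polymerase II and splicing factor 3 subunits, 0 were at 0 in every library. With depth unknown, that does not tell whether the zeros of Anxa10 and Prkd1 mean absence. Trim41 (ENSMUSG00000040365, chromosome 11, 48806404 to 48817353) stood at 23.8 ± 3.04 TPM in WT and 26.6 ± 8.82 in A10KO (SD, n = 3 each). Its log2 change of 0.12 (SE 0.23, limma adjusted p = 0.899) was within the spread between libraries. The sign of that change turned to -0.13 without A10KO replicate 1. Over the alternatives its adjusted p ran from 0.685 to 0.999. The other protein kinase D genes, chosen after their values were seen, were Prkd3, at 9.60 ± 1.37 and 9.64 ± 3.20 TPM, and Prkd2, at 0.97 ± 0.552 and 1.74 ± 0.27.

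Lgals3, Tubb2b and Isg15 were lower and Id3 and Id2 higher in A10KO than in WT. Lgals3, which encodes the sugar-binding protein galectin-3, fell from 21.3 ± 2.98 to 0.127 ± 0.0981 TPM (log2 change -4.30, SE 0.20, limma adjusted p = 0.00061), a ratio of mean TPM of 168. With a pseudocount of 0.1 in place of 1 its log2 change was -6.64. Id3 and Id2 encode inhibitors of helix-loop-helix transcription factors. Id3 rose from 46.4 ± 10.8 to 295 ± 34.0 TPM (log2 change 2.66, adjusted p = 0.00529) and Id2 from 61.9 ± 13.1 to 278 ± 63.9 (2.15, adjusted p = 0.0423). Tubb2b, a beta-tubulin gene, fell from 29.6 ± 2.93 to 6.22 ± 0.0361 TPM (-2.08, adjusted p = 0.00529). Isg15, an interferon-induced ubiquitin-like protein gene, fell from 53.7 ± 5.67 to 8.83 ± 2.68 TPM (-2.51, adjusted p = 0.0207).

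These 5 genes were all that limma called among 12068, 2 higher and 3 lower in A10KO, each by at least 2-fold. Lgals3 lies on chromosome 14 (47367751 to 47386160), Id3 on chromosome 4 (136143497 to 136145755), Id2 on chromosome 12 (25093799 to 25097140), Tubb2b on chromosome 13 (34126748 to 34130466) and Isg15 on chromosome 4 (156199424 to 156200818). All 5 are annotated as protein coding. At an unadjusted p under 0.05 there were 1066 genes, 309 higher and 757 lower. The groups did not overlap for 677 genes that were higher and 1390 that were lower in A10KO, 17.1% of those tested against 10% by chance. The excess of lower genes was counted on TPM as deposited, where the median log2 change over all genes was -0.04. Whether the excess changes with the scaling is not shown here. The median over all genes was 0.01 under median-of-ratios scaling, 0 under trimmed-mean scaling and 0.02 with mitochondrial transcripts removed. In the planned leave-one-out fits, Lgals3 was under the filter whenever a WT library was left out, because it was below 1 TPM in every A10KO library. It was not tested there. The count of called genes was 1 without WT replicate 1 or 2, 2 without WT replicate 3, 9 without A10KO replicate 1, 20 without A10KO replicate 13 and 5 without A10KO replicate 14. With the tested genes kept, a form chosen after these counts were seen, it was 2, 2, 3, 8, 5 and 5, with Id3 and Lgals3 called each time, whereas Tubb2b and Isg15 missed the threshold without any WT library, Isg15 also without A10KO replicate 1, and Id2 without any library but A10KO replicate 1. Isg15 and Id2 also missed it with no filter and under quantile normalization.

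**Figure D1:**
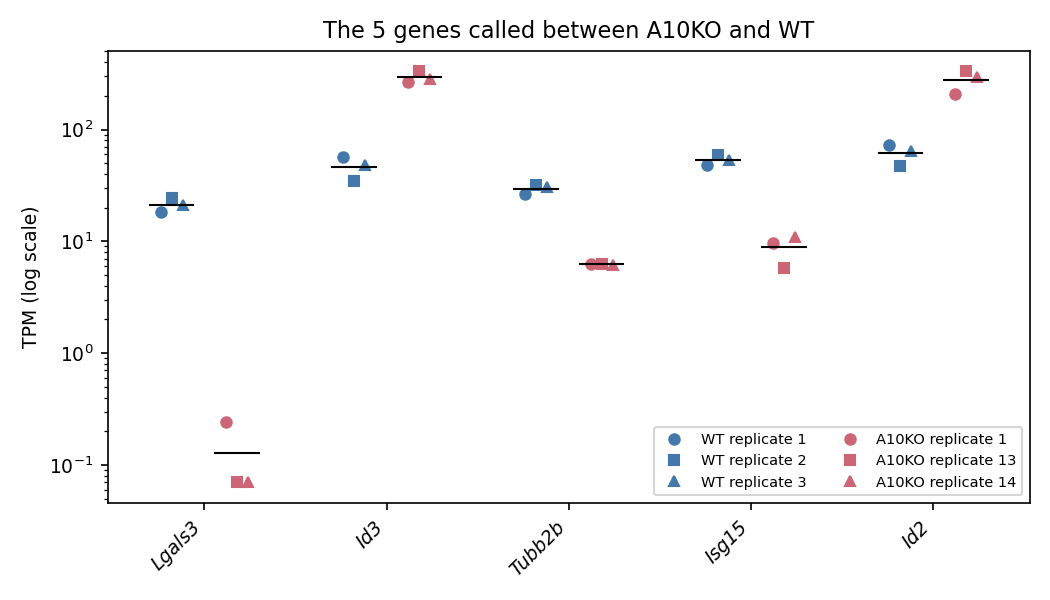
TPM on a log scale for the 5 called genes, with 1 point per library and a horizontal line at the mean of each group of 3. For each gene the WT and A10KO libraries do not overlap, and Lgals3 is between 0.07 and 0.24 TPM in the A10KO libraries.

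Genes of the type I interferon response were lower in A10KO as a group. Of 31 tested members, 24 fell adjusted over the list alone and 1, Isg15, over all genes tested, and 30 had a log2 change below 0. The median log2 change was -0.90, and the medians per library were -0.98, -0.96 and -0.84 in A10KO replicates 1, 13 and 14. Further members were chosen after their values were seen. Usp18, which removes ISG15 from proteins, went from 13.2 ± 1.90 to 1.53 ± 1.12 TPM (limma adjusted p = 0.000957 over the list alone, 0.116 over all genes). Bst2, which encodes the antiviral protein tetherin, went from 330 ± 27.8 to 122 ± 34.1 (adjusted p = 0.00115 over the list alone). Other members changed little. Ifit2 stood at 12.2 ± 1.69 and 12.1 ± 3.3 TPM, Herc6 at 13.1 ± 0.928 and 12 ± 4.51, and Stat2 at 7.91 ± 3.37 and 7.55 ± 1.02. Camera called the list lower (adjusted p = 1.01e-22), with an adjusted p = 0.176 with an estimated correlation and 0.0117 by fry. Among leukocyte markers, Ptprc and Tyrobp were at 0 TPM in all WT libraries, whereas Cd68 stood at 3.97 ± 1.35 TPM in WT and 1.01 ± 0.24 in A10KO and Laptm5 at 0.51 ± 0.214 and 0.0933 ± 0.0945, both chosen after their values were seen. The 3 lists fixed as signs of RNA quality also differed between the groups, with medians of 0.64 for mitochondrially encoded transcripts, -0.40 for immediate early genes and -0.53 for histones (camera adjusted p = 1.42e-07, 0.0122 and 0.0122, and adjusted p = 0.501 for each with an estimated correlation). In A10KO replicates 1, 13 and 14 the mitochondrial medians were 0.50, 1.21 and 0.25 and the histone medians -0.19, -1.09 and -0.25. Both were farthest from 0 in replicate 13, unlike the interferon medians. Immediate early medians were -0.36, -0.36 and -0.49.

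**Figure D2:**
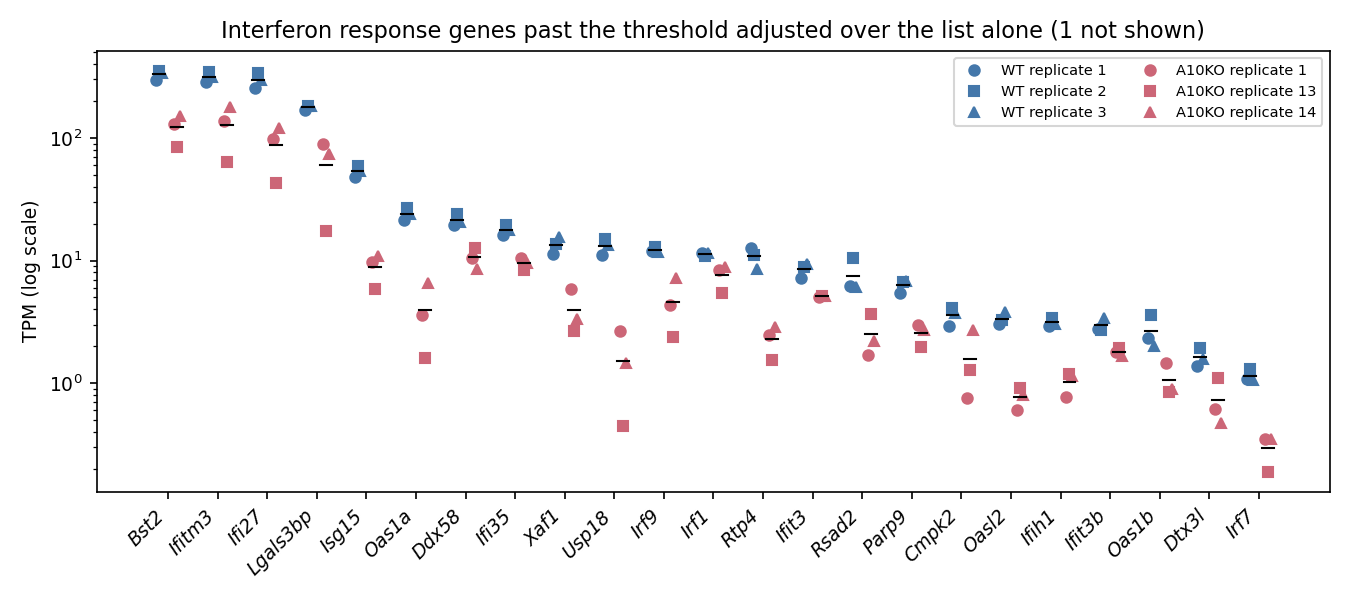
TPM on a log scale for the 24 interferon response genes past the threshold adjusted over the list alone, of which 1 is not shown, ordered by WT mean, with 1 point per library and a line at each group mean. Bst2 stands at a mean of 330 TPM in WT and 122 in A10KO, and Irf7, chosen after its values were seen, at 1.15 and 0.297.

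Antigen presentation genes were also lower. Of 15 tested, 6 fell adjusted over the list alone and 0 over all genes, and the median log2 change was -0.55. B2m, the light chain of MHC class I, went from 541 ± 45.6 to 338 ± 66.8 TPM (limma adjusted p = 0.0209 over the list alone), whereas Calr, a chaperone of the endoplasmic reticulum, stood at 736 ± 96.8 and 765 ± 91.9. Among genes chosen after their values were seen, Tap1, a peptide transporter gene, went from 6.89 ± 0.708 to 2.68 ± 0.54 (adjusted p = 0.00567) and H2-D1, an MHC class I heavy chain gene, from 79.1 ± 7.15 to 42.6 ± 7.26 (adjusted p = 0.00567). Camera gave an adjusted p = 7.75e-05, and the adjusted p = 0.501 with an estimated correlation. With no filter the median was -0.36. The 3 RNA quality lists moved beside these genes as well. Antigen presentation medians were -0.63, -0.47 and -0.37 in A10KO replicates 1, 13 and 14, and so were not farthest from 0 in replicate 13.

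Calcium-binding S100 genes and the remaining annexins were lower in the camera test. In the S100 family 3 of 7 tested members fell adjusted over the list alone, with 0 over all genes and a median log2 change of -0.84. S100a11 went from 402 ± 5.08 to 230 ± 64.6 TPM (limma adjusted p = 0.0110 over the list alone) and S100a10, the partner of annexin A2, from 173 ± 2.64 to 82.6 ± 10.4 (adjusted p = 0.000288). The S100 medians per library were -0.04, -1.23 and -0.72 in A10KO replicates 1, 13 and 14. In the annexin family 1 of 8 members fell adjusted over the list alone and 0 over all genes, with a median of -0.31. That member was Anxa1, at 103 ± 10.4 and 52.1 ± 19.4 TPM (adjusted p = 0.0321), chosen after its values were seen. Anxa2 stood at 325 ± 52.6 and 219 ± 56.2 TPM, and Anxa5 at 379 ± 20.3 and 280 ± 83.1. Camera gave adjusted p = 0.00175 for S100 and 0.0122 for annexins, the adjusted p = 0.501 for each with an estimated correlation, and both calls ended without A10KO replicate 14. With no filter the S100 median was -0.20. Beside these lists, mitochondrially encoded transcripts took 7.93%, 14.7% and 7.37% of TPM in A10KO replicates 1, 13 and 14 and at most 6.56% in WT.

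The list of TGF-beta targets held Id3 and Id2, the called genes that rose. Of 20 tested, 4 rose adjusted over the list alone (Id3, Id2, Id1 and Smad6) and 2 of these over all genes. Id1 stood at 13.4 ± 0.649 TPM in WT and 30.1 ± 5.39 in A10KO, and Smad6, an inhibitor of BMP signalling, at 5.38 ± 0.635 and 16.8 ± 4.48. Id1 and Smad6 were chosen after their values were seen. The list's median log2 change was -0.04 and its mean 0.29, and camera tested it as higher (adjusted p = 0.0315, and adjusted p = 0.553 with an estimated correlation). The call ended without any 1 of the A10KO libraries, with no filter, with chromosome medians removed and under median-of-ratios, trimmed-mean and quantile scaling, where the median was 0 to 0.02. The RNA quality lists (mitochondrial median 0.64) moved beside this list too.

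Of the lists tied to cell state and invasion, matrix proteases and actin genes were called lower by camera, and melanocyte, mesenchymal and dedifferentiated state genes were not called. Melanocyte differentiation genes had a median log2 change of 0.03 over 23 members (camera adjusted p = 0.0621), of which 1 rose adjusted over the list alone and 0 over all genes. Tyrp1 stood at 2980 ± 101 and 3320 ± 772 TPM and Mlana at 2500 ± 367 and 2990 ± 517. Of 8 mesenchymal genes, 2 fell adjusted over the list alone and 0 over all genes (camera adjusted p = 0.0937). They were Vim, the intermediate filament vimentin, from 2810 ± 87.9 to 1670 ± 369 TPM (adjusted p = 0.0127), and Fn1, fibronectin, from 70.8 ± 14.2 to 36.8 ± 6.20 (adjusted p = 0.0114), the latter chosen after its values were seen. Sparc, with the highest mean after Vim, stood at 440 ± 20.9 and 393 ± 38.4 TPM. Of 8 genes of a dedifferentiated or invasive state, 1, Jun, fell adjusted over the list alone and 0 over all genes (median -0.17, camera adjusted p = 0.386). Cd44, the member with the highest mean, stood at 69.6 ± 9.89 and 62.3 ± 7.28 TPM. Among 18 genes for matrix proteases and their inhibitors, 1 fell adjusted over the list alone and 0 over all genes. That was Ctsb, the lysosomal protease cathepsin B, from 237 ± 22.1 to 132 ± 9.08 TPM (adjusted p = 0.00317). Mmp14, with the next highest mean in that list, stood at 144 ± 10.5 and 133 ± 22 TPM. The list was called lower (median -0.24, camera adjusted p = 0.0109, and adjusted p = 0.501 with an estimated correlation), and without A10KO replicate 14 it was not. Actin cytoskeleton genes were called lower with a median of -0.17 over 32 members (camera adjusted p = 0.00147, and adjusted p = 0.501 with an estimated correlation), and 0 members passed by either adjustment. That median was -0.10 without A10KO replicate 1 or with mitochondrial transcripts removed, and -0.11 under median-of-ratios scaling. The RNA quality lists (mitochondrial median 0.64) moved beside the protease and actin lists too. Actb stood at 1440 ± 64.6 and 1320 ± 255 TPM.

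Camera called 17 of the 37 lists, and with an estimated correlation 0 were called. Fry called 2, the interferon list and NRF2 targets (adjusted p = 0.0286, median 0.05). Beyond those above, and with the 3 RNA quality lists included, cholesterol synthesis (median -0.33), glycolysis and hypoxia (-0.30), immediate early genes (-0.40), histones (-0.53), lysosome and autophagy (-0.11), ribosomal proteins (-0.18) and collagens (-0.29) were lower. Ribosome biogenesis (0.15), MAPK feedback genes (0.21) and mitochondrially encoded transcripts (0.64) were higher. Adjusted over the list alone, 1 mitochondrial transcript rose (mt-Nd3), as did 1 MAPK feedback gene (Etv5), whereas 2 immediate early genes (Jun and Atf3), 1 histone gene (Hist1h2bc) and 1 lysosomal gene (Ctsb) fell, with 0 over all genes. Of these, mt-Nd3, Etv5 and Atf3 were chosen after their values were seen. Jun went from 39.7 ± 5.77 to 17.3 ± 7.08 TPM and Hist1h2bc from 41.6 ± 4.47 to 17.8 ± 8.05. Adjusted p-values of these 10 lists ran from 1.42e-07 to 0.0447 by camera, and all were at 0.501 or more with an estimated correlation. Without A10KO replicate 14 the count fell to 6 lists, and without A10KO replicate 13 the cholesterol, glycolysis, immediate early, histone and MAPK calls ended and the ribosomal protein list changed direction in camera (median -0.04). The glycolysis, ribosome biogenesis (median -0.03) and collagen calls ended without WT replicate 2, the collagen call also without WT replicate 3 or A10KO replicate 1, the ribosomal protein call without WT replicate 1 or 3 and under the 3 other scalings, and the MAPK call without WT replicate 1 or A10KO replicate 1, with no filter, with a 5 TPM filter, with mitochondrial transcripts removed and under quantile normalization. With array quality weights the MAPK, ribosomal protein, ribosome biogenesis and cholesterol calls ended, and the histone call ended without WT replicate 1 with the tested genes kept. Medians moved with single libraries, to -0.62 without A10KO replicate 14 and -0.15 without A10KO replicate 13 for cholesterol synthesis, and to -0.50, -0.04, -0.46 and -0.19 without WT replicate 1, WT replicate 2, A10KO replicate 1 and A10KO replicate 14 for glycolysis. They were -0.05 for collagens and -0.22 for immediate early genes without WT replicate 2, -0.18 for collagens without A10KO replicate 1, -0.30 for ribosomal proteins and 0.06 for ribosome biogenesis without A10KO replicate 14, and 0.24 for ribosome biogenesis and 0.13 for MAPK feedback without WT replicate 1. Without A10KO replicate 13 they were 0.36 for mitochondrial transcripts and 0.12 for MAPK feedback. The histone median was -0.28 with no filter and -1.16 with a 5 TPM filter, the lysosome median -0.04 with mitochondrial transcripts removed, and the cholesterol median -0.03 with array quality weights. Pdk1, a hypoxia-induced kinase gene chosen after its values were seen, was at 50.96 TPM in WT replicate 2 and 12.71 and 19.24 in the other WT libraries.

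Proliferation and respiration lists were among the 20 that camera did not call. DNA replication genes had a median log2 change of -0.01 over 36 members (camera adjusted p = 0.356) and mitosis genes -0.11 over 36 (adjusted p = 0.102), with 0 members past the threshold by either adjustment. Pcna stood at 371 ± 31.8 and 367 ± 82.8 TPM and Cdk1 at 330 ± 24.7 and 301 ± 58.0. Nuclear-encoded oxidative phosphorylation genes had a median of -0.03 over 37 members (adjusted p = 0.903) and integrins -0.01 over 9 (adjusted p = 0.8). Of 22 p53 targets, 1 fell adjusted over the list alone and 0 over all genes (median -0.07, camera adjusted p = 0.586). Of the markers of other cell types, 17 of 20 epithelial, 12 of 16 leukocyte, 9 of 12 fibroblast and 9 of 12 keratinocyte genes were under 1 TPM in every library. Of 12 endothelial markers 5 were tested, with a median of -0.05 (camera adjusted p = 0.77), and 1 rose adjusted over the list alone and 0 over all genes. That was Tek, chosen after its values were seen, at 10.4 ± 4.65 and 28.5 ± 9.08 TPM, whereas Eng stood at 126 ± 16.8 and 122 ± 16.8 and Egfl7 at 21.2 ± 2.40 and 21.3 ± 2.94.

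**Figure D3:**
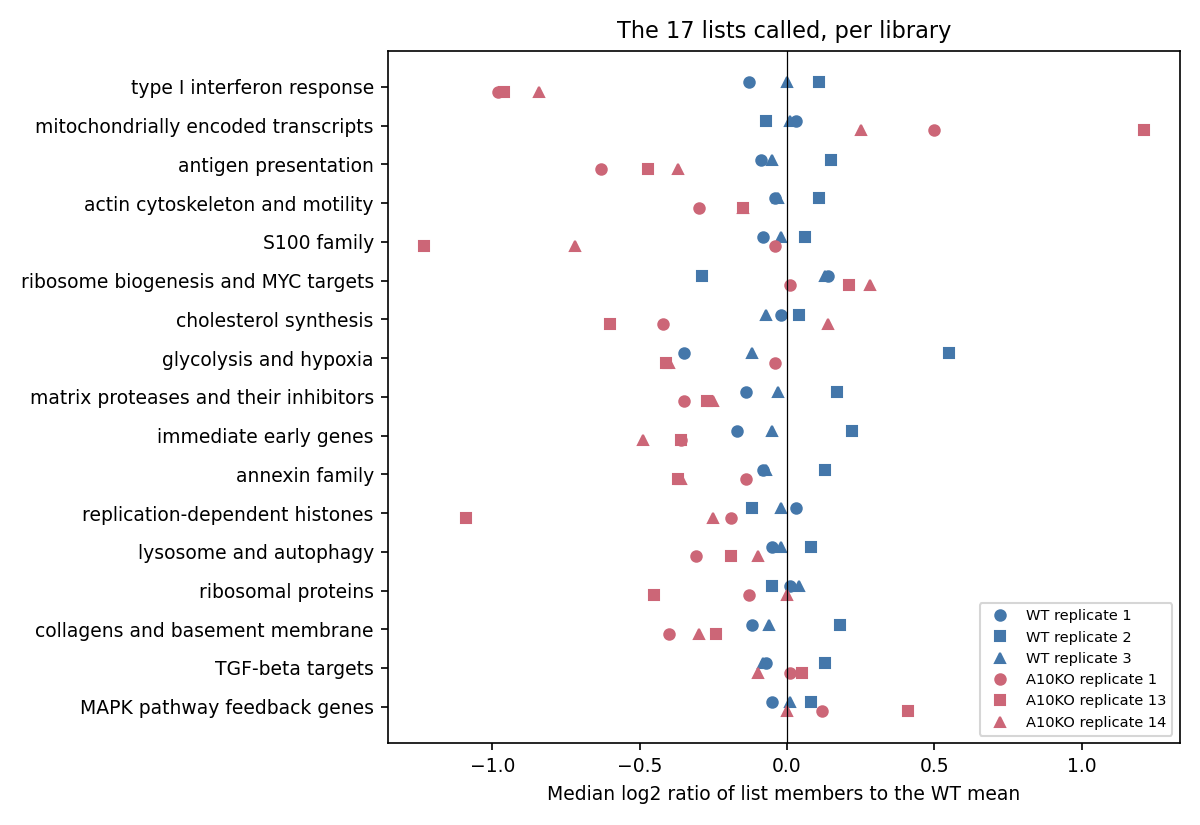
Median over list members of the log2 ratio to the WT mean, with 1 point per library, for the 17 lists called by camera. The interferon medians are -0.98, -0.96 and -0.84 in the A10KO libraries, and the mitochondrial median is 1.21 in A10KO replicate 13 against 0.50 and 0.25 in the other A10KO libraries.

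The A10KO libraries differed more among themselves than the WT libraries did. Pearson correlations across genes on the log2 scale, where genes are not independent replicates, were 0.974 to 0.984 within WT and 0.940 to 0.964 within A10KO. Between the groups they were 0.944 to 0.975. Mitochondrially encoded transcripts took 6.32% to 6.56% of TPM in WT and 7.93%, 14.7% and 7.37% in A10KO replicates 1, 13 and 14. Ribosomal protein genes took 7.50% in A10KO replicate 13 and 9.62% to 10.2% elsewhere. The first principal component, with 37.5% of the variance, set A10KO replicate 13 apart.

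Median expression differed between chromosomes by more in the A10KO libraries than in the WT libraries. In A10KO replicate 1 the chromosome medians ran from -0.32 on chromosome 12 to 0.29 on chromosome 10, with 88.7% of 345 genes on chromosome 12 below the library median. In A10KO replicate 13 they ran from -0.35 on chromosome 7 to 0.18 on chromosome 16, and in A10KO replicate 14 from -0.13 on chromosome 11 to 0.17 on chromosome 15. The SD over the 20 chromosomes was 0.168, 0.150 and 0.059 in A10KO replicates 1, 13 and 14, and 0.020, 0.029 and 0.013 in WT replicates 1, 2 and 3.

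**Figure D4:**
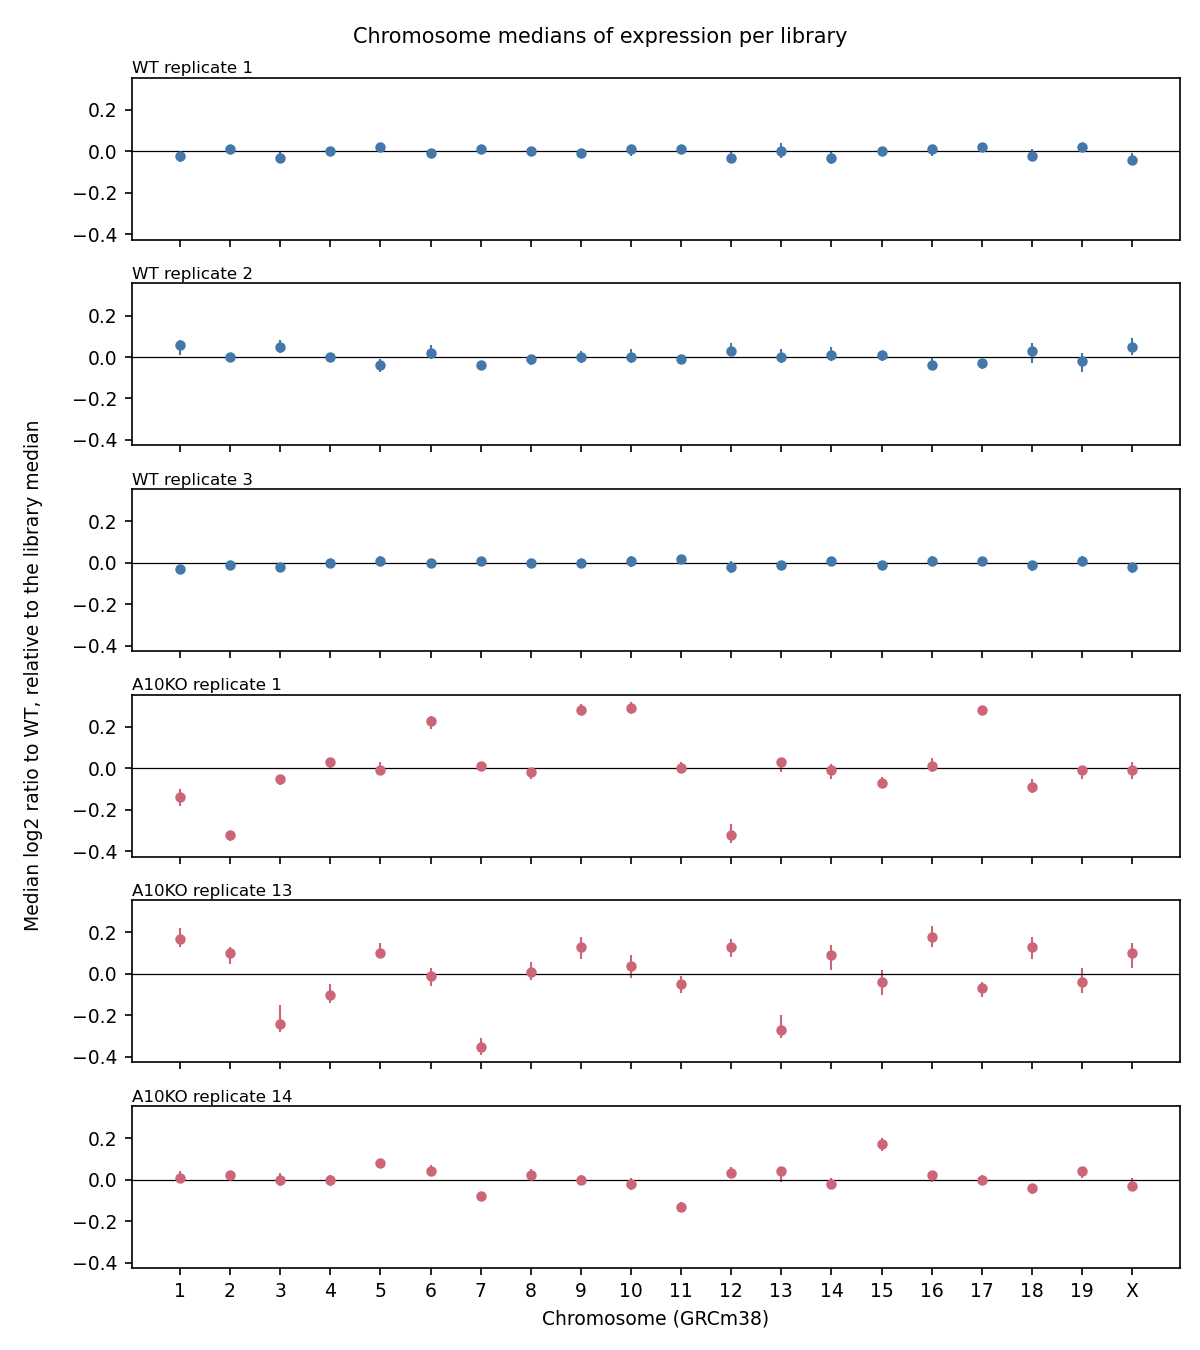
Median log2 ratio to WT of the genes on each chromosome, relative to the library median, with 95% bootstrap intervals over genes, in 1 panel per library. WT medians lie between -0.04 and 0.06, whereas A10KO replicates 1 and 13 reach -0.32 and -0.35.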

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

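The scaling, weighting, robust and chromosome settings, the 5 TPM filter, the removal of mitochondrial transcripts, the leave-one-out fits that kept the tested genes and the splits for gene counts were chosen after the data were seen. The 5 called genes were kept with a pseudocount of 0.1, a filter at 5 TPM, median-of-ratios and trimmed-mean scaling, mitochondrial transcripts removed, robust empirical Bayes and chromosome medians removed, the last of which called 6. With no filter 23617 genes were tested and 4 called, 1 higher, of which 3 were among the 5, since Isg15 and Id2 lost their calls. Quantile normalization called 3 (1 higher, 2 lower, 3 of at least 2-fold), again without Isg15 and Id2. Array quality weights called 25, 9 higher and 16 lower, 22 of at least 2-fold. The cause was not tested. In the planned leave-one-out fits, which refilter the 5 libraries, genes called ran from 1 to 20, genes higher in knockout from 1 to 8, genes lower from 0 to 12, those of at least 2-fold from 1 to 15, and lists from 6 to 17. Lgals3 was not tested in those fits that left out a WT library. With the tested genes kept, the same counts ran from 2 to 8, 1 to 2, 1 to 6, 2 to 8 and 6 to 16. Without A10KO replicate 13 the first form called 20 genes and the second 5, and the forms differ only in the genes tested. Both forms called 6 lists without A10KO replicate 14. An estimated correlation called 0 lists and fry 2. The interferon median was -0.90 with an estimated correlation (adjusted p = 0.176) and from -1.30 to -0.79 over 24 alternatives, and the other 23 kept its call. The ribosomal protein list had medians from -0.30 to -0.04 over the leave-one-out fits, the latter with the opposite direction in camera without A10KO replicate 13 in both forms. Trim41 ran from -0.13 to 0.26, below 0 without A10KO replicate 1 in both forms, with adjusted p from 0.685 to 0.999 over its 22 alternatives. Over 54 genes followed across alternatives there were 1169 values, of which 28 lost and 22 gained a call and 2 changed sign, both Trim41. Count-based alternatives were not run because the unit is TPM. No paired analysis was possible because the groups share only the number 1. Depth is unknown, so its limits cannot be stated. The 6 libraries split into groups of 3 in 10 ways, too few for a share under 0.05. In the real split 5 genes were called against at most 1 in the others, 2 were higher and 3 lower against at most 1 in one direction, 5 changed at least 2-fold against at most 1, and 17 lists were called against at most 13.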

Other observations

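The tests of the first against the second part of each chromosome in single libraries, and of TPM composition for the interferon genes, were chosen after the results were seen, as were the genes named in this part. The joint test of these parts in A10KO replicates 1 and 13 and the other tests were set before their results were seen. Of the BMP target genes tested below, however, Smad7, Bambi, Zeb2 and Eng were also members of the lists tested above.

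Several genes outside the lists had groups that did not overlap but missed the threshold over all genes. Nppb, a natriuretic peptide gene, stood at 31.0 ± 3.10 TPM in WT and 6.86 ± 3.25 in A10KO (SD, n = 3 each, limma adjusted p = 0.116). Anpep, an aminopeptidase gene, stood at 20.3 ± 1.52 and 9 ± 0.542 (adjusted p = 0.116), and Batf, a transcription factor gene, at 5.41 ± 1.32 and 0.517 ± 0.536 (adjusted p = 0.127). Tspan7 stood at 9.57 ± 0.595 and 21.7 ± 2.79 (adjusted p = 0.125). The genes next to Lgals3 on chromosome 14 did not share its difference. Dlgap5, which starts at 47387779, stood at 46.3 ± 9.92 and 42.2 ± 2.60 TPM, and Mapk1ip1l, which ends at 47323204, at 23.3 ± 1.43 and 23.9 ± 6.06. Nek1 was at 633.55 TPM in A10KO replicate 13 and 120.38 to 199.09 in the other libraries, and Col19a1 at 4599.13 against 1391.79 to 2137.61. Grhl2, an epithelial transcription factor gene, had means of 34.2 TPM in WT and 60.7 in A10KO.

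The chromosome shifts differed between the A10KO libraries. Chance placement of shifted genes is argued against by permutation p = 1e-04 in each A10KO library, the smallest that 10000 reassignments can give. The same p was reached in WT replicates 1 and 2 with SDs of 0.020 and 0.029, so the size of the SD separates the groups rather than that p. GC content and gene length are argued against as the whole cause, because after both trends were removed the smaller SD of A10KO replicates 1 and 13 was 0.143. The joint test set beforehand for whole-chromosome gain or loss did not decide, since the smaller r between the first and the second part of each chromosome in replicates 1 and 13 was 0.40 (permutation p = 0.08). Taken singly afterwards, Pearson r over 20 chromosomes was 0.96 in replicate 1 (rho 0.88, 0.95 without the 2 farthest), 0.40 in replicate 13 (rho 0.35, 0.20) and 0.76 in replicate 14 (rho 0.56, 0.51), with Benjamini-Hochberg values over 6 libraries of 6e-05, 0.16 and 0.00054, so that copy number differences may underlie the shifts in replicates 1 and 14, a hypothesis that no DNA measurement tested.

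The lower interferon genes were set against 3 technical explanations. RNA quality was not among them and was not tested as a cause, although the lists fixed as its signs also differed between the groups. Of these, the mitochondrial and histone medians were farthest from 0 in A10KO replicate 13 (1.21 and -1.09). The interferon list had medians of -0.98, -0.96 and -0.84 in A10KO replicates 1, 13 and 14. TPM composition is argued against, because the list's median was -0.86 under median-of-ratios scaling. Leukocytes in the WT cultures are argued against, because 3 of 4 markers had a WT mean under 1 TPM (Ptprc 0, Tyrobp 0, Laptm5 0.51), although Laptm5 was at 0.0933 in A10KO and Cd68, outside the 4, at 3.97 in WT and 1.01 in A10KO, whereas Coro1a stood at 1.13 in WT and 2.80 in A10KO. Chromosome shifts are argued against, because the median was -0.88 with chromosome medians removed. Loss of annexin A10 and differences between separately derived cell populations may each account for the pattern and were not tested apart, since the labels do not say how the A10KO libraries were derived. Anxa10 was listed at 0 TPM in every library, WT included, so its loss could not be seen in these data. The chromosome shifts differed between the A10KO libraries.

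Id1, Id2, Id3, Smad6, Smad9 and Atoh8 had higher means in A10KO, and a rise across BMP and SMAD1/5 target genes was tested as a candidate explanation. Smad9 stood at 1.14 ± 0.0173 and 3.63 ± 0.355 TPM and Atoh8 at 18.5 ± 6.41 and 75.9 ± 30.1. In 8 further target genes the median log2 change was -0.01 (SD of members 0.26, with 3 above 0). The median set as needed for such a rise was 0.3, which was not reached. The highest of the 8 changes was 0.38, against at least 1.1 in the 6 genes named first. Adjusted over the list alone, 0 of the 8 rose. These 8 genes did not show a rise of that size, with Bambi and Runx2 at 1.70 and 2.76 TPM in WT. Smad7, Bambi, Zeb2 and Eng, with changes of 0.063, -0.007, -0.005 and -0.046, were already members of the lists above. Their values near 0 held the median down, so the test does not decide on a rise across BMP target genes. The 8 genes leave out the 6 named first, so a rise limited to fewer target genes stays open.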
